A study of Brassica rapa with 30 samples.

How the data were processed

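RNA was sequenced from whole plants of Brassica rapa cultivars Chiifu and LP08, 3 libraries for each of 5 treatments in each cultivar, 30 in all. Per the labels' protocols, total RNA was extracted with a column kit and treated with DNase, libraries were made with the TruSeq Stranded mRNA kit, and they were read on an Illumina NovaSeq instrument. The submitters' processing notes name FastQC, TopHat2, HTSeq and edgeR, without versions. The genome build, the annotation and the strand setting used for counting are not given in the sources used here.

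The authors deposited 1 table per library with the whole-number count of reads assigned to each gene, not normalized. Each deposited count table held 42186 gene rows, of which 41018 had IDs beginning with Bra and 1168 with ENSRNA, and 5 summary rows of reads that were not assigned. The summary rows stayed out of library sizes and tests. Reads on no gene were 6.91 to 11.5% of the alignments counted, alignments at several places 2.67 to 7.29% and reads on overlapping genes at most 0.0591%. Genes whose reads fall on near-identical copies are therefore counted in part, and in a genome with many duplicated genes, as in Brassica, the levels of single copies are uncertain. The same holds for overlapping genes, and for antisense genes as the strand setting is unknown. Rows beginning with ENSRNA took 0.0414 to 0.653% of the counts. No pair of libraries in a group was a duplicate, as Pearson's chi-square of their counts per degree of freedom was 7.28 to 134.

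Gene names were sought in a table of RefSeq genes of the assembly CAAS_Brap_v3.01 with 51589 rows, through locus tags, synonyms and accessions. It paired 1 of the 42186 IDs with a name, Bra000116 with SWEET9, known in Brassica relatives as a nectary sugar transporter. This gene had 0 counts in all 30 libraries, which allows up to 0.009 CPM in the summed counts of Chiifu and 0.00999 CPM in those of LP08. For that reason the 22 gene lists and the copies of FLC, FT, SOC1 and VIN3 that were fixed before the data were examined could not be tested, and the rule for named genes, which took the 5 genes with the greatest change per direction among those with a name, selected none. Features are printed by ID instead, at most 2 per direction and comparison, chosen after their values were seen among those with at least 10 counts in every library compared and at least 5 CPM in 1 of the groups. Any of them may belong to these lists or be one of these copies. Checks of gene length and GC content were void, as no gene had a length or sequence here.

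Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test on all 30 libraries and 1 mean per group, so that all groups share the estimate of spread of each gene. Libraries were scaled with TMM factors, and rows with low counts were removed by filterByExpr, which left 28712, among them 105 beginning with ENSRNA. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called with an adjusted p below 0.05. The 15 comparisons were LP08 against Chiifu without cold, each of 4 treatments against NV in each cultivar, V40T10 against V40 in each cultivar, and the difference between the cultivars' responses at each of the 4 treatments, as an interaction term. Standard errors of log2 fold changes were taken from the F statistic. CPM values are in counts-per-million units of the TMM-scaled library size, with SDs over 3 libraries, and log2 CPM used a prior count of 2. Overlaps of calls were set beside the product of both list lengths over the number of genes tested. Limits from a count of 0 use 3 counts and, like the SDs of low counts, cover counting error only, since reads copied by PCR are not independent molecules.

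Counts were simulated with the LP08 NV means in all groups, 1 spread per gene and the library sizes of these data. They held neither the difference between the cultivars nor the wider spread of Chiifu NV, so false calls where Chiifu NV enters were not assessed. The model was tested on these counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold in LP08 V1. For LP08 V1 against NV, over 25994 genes, it recovered 8.96% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 95.5% of those changed 4-fold, and 4.46% of its calls were false. For the difference between cultivars at V1 it recovered 1.49, 29.9 and 81.8%, with 1.32% of calls false. The interaction recovered less than the comparison within a cultivar at each fold. As far fewer genes were changed here than in the data, the adjusted threshold was stricter, and these shares do not carry over to the real comparisons, where 6080 of the 12127 genes called for LP08 V1 against NV had a change of 2-fold or more. A further 8 sets with unchanged groups held each group at the NV means of its own cultivar, so the cultivars differed in them. They too used 1 spread per gene, without the wider spread of Chiifu NV.

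Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, fits of the compared groups alone, the replicate number as a block, a minimum log2 fold change of 1, the removal of genes absent from one cultivar, and each library left out in turn. Added after the data were seen were limma 3.58.1 voom with weights per group, Chiifu NV replicates 2 and 3 left out together, all libraries thinned to 16926920 counts, V40 as the baseline of the V40T10 interaction, scaling of the V40 and V40T10 interactions by library total, and log2 shifts of the LP08 libraries in them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.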

Results

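Transcript levels were measured in whole plants of 2 Brassica rapa cultivars, Chiifu, labelled late flowering, and LP08, labelled early flowering. Plants raised in a greenhouse for 3 weeks were sampled without cold (NV), after 1 day (V1), 20 days (V20) or 40 days (V40) of cold, or after 40 days of cold and 10 days of return to warmth (V40T10). Prolonged cold, or vernalization, makes many Brassica plants competent to flower. Each of the 10 groups held 3 libraries. The counts assigned to genes ranged from 16926920 to 26595834 per library, and between 29285 and 31411 genes had at least 1 count. A level of 0 in a library of this depth allows up to 0.113 to 0.177 counts-per-million units (CPM), as far as counting error goes. The labels do not say that the libraries of a group came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. No group of untreated plants as old as the cold-treated ones was among the samples, so each comparison with NV joins the treatment with the time that passed.

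Cultivar was the largest source of variation. The first principal component held 47.7% of the variance of log2 CPM and separated all 15 Chiifu libraries from all 15 LP08 libraries. The second component, with 16.9%, separated the libraries of plants taken from the cold (V1, V20 and V40) from those of plants kept in or returned to warmth (NV and V40T10) in both cultivars. Libraries of a group correlated at 0.971 or more across genes, except in Chiifu NV, where the 3 pairs gave 0.912 to 0.947. The SD over genes of a library's deviation from its group mean was 0.56 to 0.71 on the log2 scale in Chiifu NV and 0.19 to 0.38 in all other groups, and this wider spread enters every comparison that uses Chiifu NV.

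**Figure D1:**
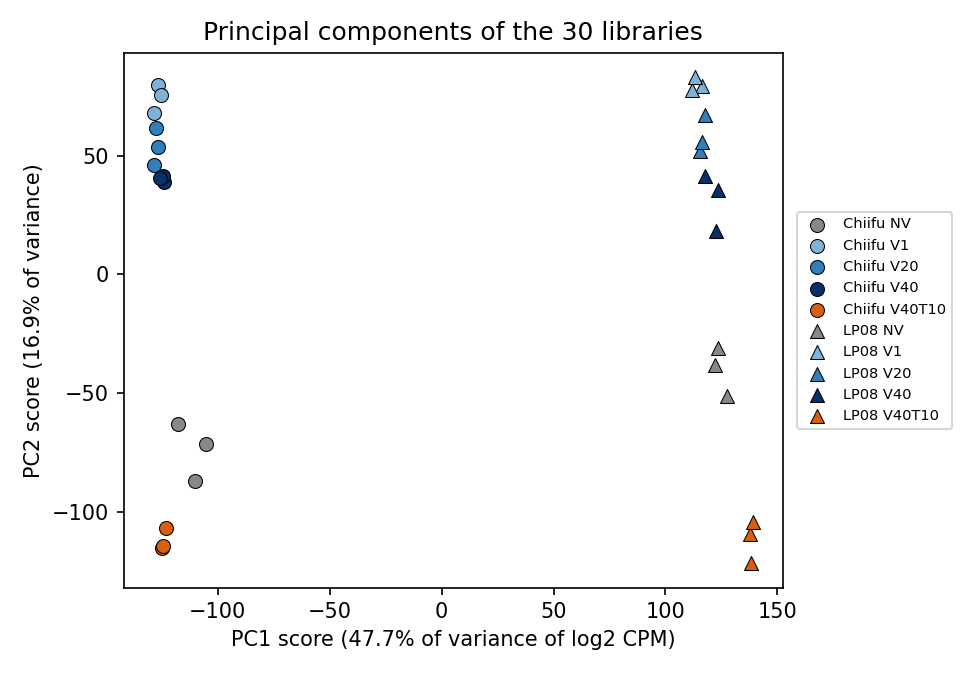
Scores of the 30 libraries on the first 2 principal components of log2 CPM, with circles for Chiifu, triangles for LP08 and one colour per treatment. The horizontal axis (47.7% of the variance) separates the cultivars and the vertical axis (16.9%) separates V1, V20 and V40 from NV and V40T10.

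**Figure D2:**
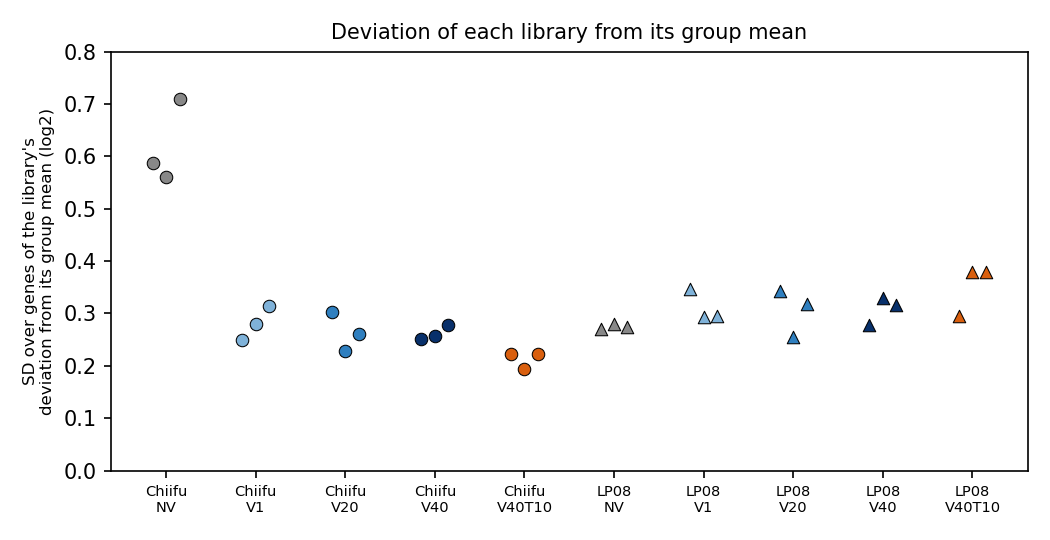
Each point is 1 library, placed by the SD over genes of its deviation from its group mean on the log2 scale. The 3 Chiifu NV libraries lie at 0.56 to 0.71, above the 0.19 to 0.38 of the other 27.

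The first comparison asked how the early- and the late-flowering cultivar differed before any cold. In LP08, 5968 of the 28712 genes tested were higher than in Chiifu and 6964 were lower, and at a difference of 2-fold or more the numbers were 2728 and 4372. The feature Bra014317, whose name is not given by the reference used here, stood at 774 ± 76.2 CPM in LP08 and 4.88 ± 1.47 CPM in Chiifu (SD, n = 3 each). It was 157-fold higher in LP08, a log2 difference of 7.30 with a standard error of 0.31 and an edgeR adjusted p of 2.41e-15. The feature Bra034717 showed the opposite, with 0.955 ± 0.243 CPM in LP08 and 129 ± 35.2 CPM in Chiifu (n = 3 each), 134-fold lower in LP08. Over all 15 libraries of each cultivar, 164 genes with a mean of at least 5 CPM in Chiifu had at most 3 counts in LP08, and 95 genes with at least 5 CPM in LP08 had at most 3 counts in Chiifu. These were 0.897% and 0.546% of the genes at that level, with median levels of 10.9 and 9.5 CPM. Whether such low counts came from little transcript or from sequences that differ from the reference was not tested. The total of 12932 genes came from a fit in which all groups share 1 estimate of spread per gene. It was 5121 when the spread came from the compared groups alone and 5563 with limma voom weights per group.

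After 1 day of cold, levels moved in both cultivars and mostly together. In Chiifu, 6398 genes rose and 8003 fell against NV, and in LP08, 5973 rose and 6154 fell. In both cultivars 3991 genes rose and 4290 fell, where independent lists of these lengths would share 1331 and 1715. Another 89 genes rose in Chiifu and fell in LP08, and 155 did the reverse. These became 199 and 267 without Chiifu NV replicate 1, and the 155 became 102 without Chiifu V1 replicate 2 and 103 without LP08 NV replicate 3. Across genes, which are not independent replicates, the log2 fold changes of the cultivars correlated at 0.593. The feature Bra000265 rose from 3.36 ± 1.28 to 2690 ± 215 CPM in Chiifu and from 3.39 ± 1.47 to 2070 ± 223 CPM in LP08 (SD, n = 3 each). These were 799-fold and 611-fold increases, with log2 changes of 9.64 ± 0.50 and 9.26 ± 0.49 (SE) and edgeR adjusted p-values of 1.38e-13 and 5.41e-13. Bra018907 fell from 148 ± 73.6 to 2.79 ± 0.114 CPM in Chiifu and from 140 ± 14.8 to 4.59 ± 1.74 CPM in LP08, 53.1-fold and 30.7-fold lower. With the spread taken from the compared groups alone, the Chiifu count was 6780 instead of 14401, the numbers shared by the cultivars were 2472 and 2644, and those that went in opposite directions 24 and 57. The LP08 count was then 13225 instead of 12127, so which cultivar had more genes depended on the spread used. All features printed here were chosen after their values were seen, for the greatest changes. Except for differences between the cultivars' responses, they came from those whose libraries did not overlap between the groups compared. Features for V1, V40 and V40T10 against NV also had to be called in the same direction in both cultivars. They were ranked by the smaller of both cultivars' changes, so their agreement between the cultivars was fixed by the choice. Not every chosen feature is described with its levels. Left out were Bra018969, ranked first for lower at V40, and Bra030917, ranked first for a higher change in LP08 at V40T10. Without Chiifu NV replicate 2, the fall of Bra018969 in Chiifu was 107-fold instead of 1070-fold. The log2 difference of Bra030917 was then 3.55 instead of 5.21, with an edgeR adjusted p of 0.0725.

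**Figure D3:**
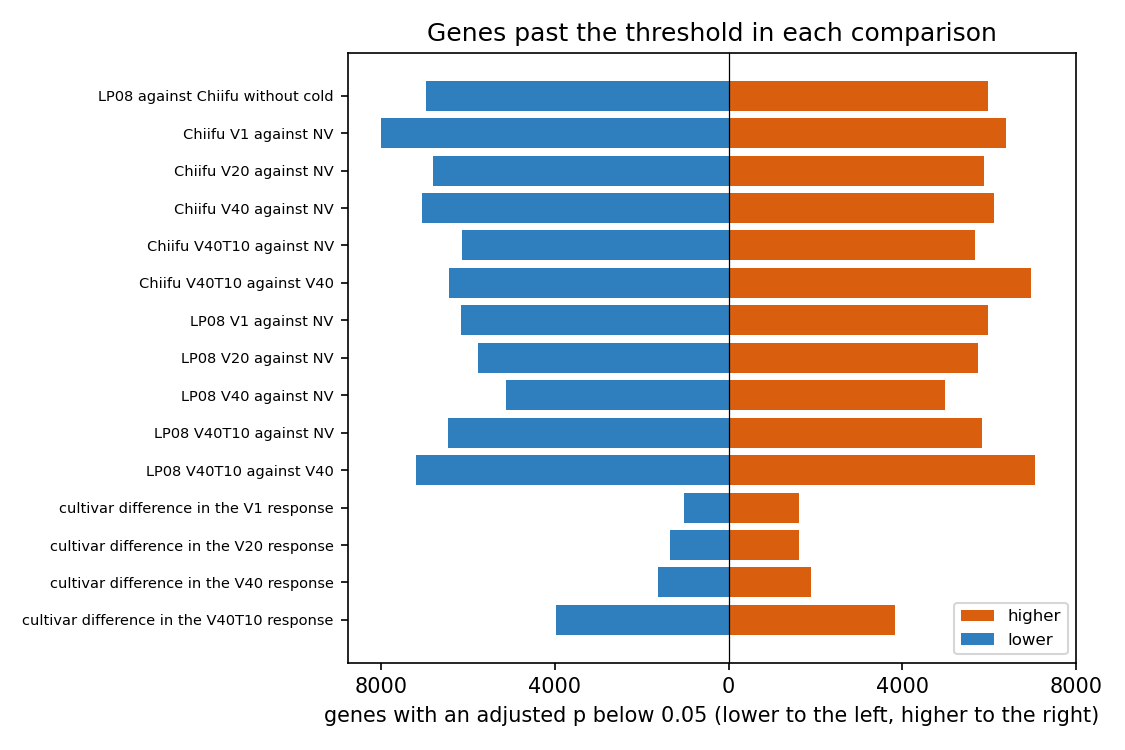
Number of genes past an adjusted p of 0.05 in each of the 15 comparisons, with genes that were higher to the right of 0 and genes that were lower to the left. Bars of the responses to cold run from 4985 to 8003 genes per direction, and the tests of a difference between the cultivars' responses rise from 2646 genes in all at V1 to 7819 at V40T10.

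After 20 and 40 days of cold the responses stayed wide, and part of them was already present at 1 day. In Chiifu, 5890 genes were higher and 6800 lower at V20 than at NV, and 6106 were higher and 7061 lower at V40. In LP08 the numbers were 5757 and 5764 at V20, and 4985 and 5130 at V40. The cultivars shared 3375 genes that rose and 3596 that fell at V20, and 2913 and 3218 at V40, where independent lists would share 1181, 1365, 1060 and 1262. The correlation of log2 fold changes across genes was 0.551 at V20 and 0.537 at V40. In Chiifu 3197 genes were higher at all of V1, V20 and V40 and 4027 were lower at all of them, and in LP08 these numbers were 2287 and 2569. In both cultivars at once, 1350 genes were higher and 1534 lower at all 3 times. A further 1738 genes in Chiifu and 1838 in LP08 were higher at V20 and V40 without being called higher at V1, and 1651 and 1703 were lower in that way.

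The feature Bra000263 stood at 23.8 ± 1.83 CPM without cold and 3080 ± 298 CPM at V40 in Chiifu, and at 16.5 ± 2.71 and 1270 ± 239 CPM in LP08 (SD, n = 3 each), 129-fold and 76.7-fold higher. Bra000265 was still at 1560 ± 128 CPM in Chiifu and 544 ± 83.3 CPM in LP08 after 40 days. Mean levels of Bra021222 fell with time in the cold, in Chiifu from 109 ± 34.8 CPM at NV to 38.5 ± 2.19 at V1, 4.57 ± 2.53 at V20 and 1.58 ± 1.37 at V40. In LP08 its levels were 120 ± 14.8, 90.9 ± 30.9, 5.81 ± 3.09 and 1.67 ± 0.904 CPM at these times. Its change at V1 in LP08 was not called (edgeR adjusted p 0.498), and no test of its step from V20 to V40 is given here. The fall to V40 was 68-fold in Chiifu (137-fold without Chiifu V40 replicate 3) and 71.6-fold in LP08, with edgeR adjusted p-values of 7.38e-09 and 1.22e-08. With the spread from the compared groups alone, the Chiifu totals of 12690 at V20 and 13167 at V40 became 4996 and 5267, and with voom weights per group 4848 and 5348. The LP08 totals of 11521 and 10115 became 12890 and 10697, and with voom weights per group 14279 and 12083. Chiifu thus had more called genes than LP08 only in the fit of all groups. With the compared groups alone, 999 genes in Chiifu were higher and 1442 lower at all of V1, V20 and V40. In both cultivars at once these numbers were 685 and 844. A further 688 and 797 in Chiifu were higher or lower at V20 and V40 without a call in that direction at V1.

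After 10 days of warmth, plants of both cultivars differed from NV plants in about as many genes as in the cold, and the cultivars shared fewer of them. In Chiifu 5674 genes were higher and 6128 lower at V40T10 than at NV, and in LP08 5833 and 6459. Both cultivars shared 2549 higher and 2431 lower genes, against 1153 and 1379 for independent lists, and 508 genes rose in Chiifu and fell in LP08 (309 without Chiifu V40T10 replicate 3), while 430 did the reverse. The correlation of log2 fold changes across genes was 0.323. Bra019964 rose from 6.88 ± 5.53 CPM at NV to 210 ± 12.5 CPM at V40T10 in Chiifu and from 8.2 ± 0.81 to 189 ± 30.8 CPM in LP08 (SD, n = 3 each), 31-fold (52.4-fold without Chiifu NV replicate 3) and 23.1-fold higher. It reached 55.4 ± 8.33 CPM in LP08 at V20, when Chiifu was at 3.51 ± 0.582 CPM, and the difference between the cultivars' V20 responses was 3.70 on the log2 scale (SE 0.57, edgeR adjusted p 0.000165), and 2.92 without Chiifu NV replicate 3. Bra006051 fell from 89.5 ± 20.2 CPM at NV to 2.12 ± 0.422 at V20 and 0.071 ± 0.0503 at V40 in Chiifu, and was at 0.573 ± 0.0577 CPM after the warm period, 154-fold below NV. In LP08 it went from 90.7 ± 7.21 to 4.69 ± 1.85 and 0.303 ± 0.327 CPM, and was at 1.31 ± 0.494 CPM at V40T10, 70.3-fold below NV. Its edgeR adjusted p-values at V40T10 against NV were 7.74e-13 in Chiifu and 1.51e-11 in LP08. The Chiifu total of 11802 was 4312 with the spread of the compared groups alone and 4023 with voom weights per group. The LP08 total of 12292 was 12737 and 13983 with these settings.

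**Figure D4:**
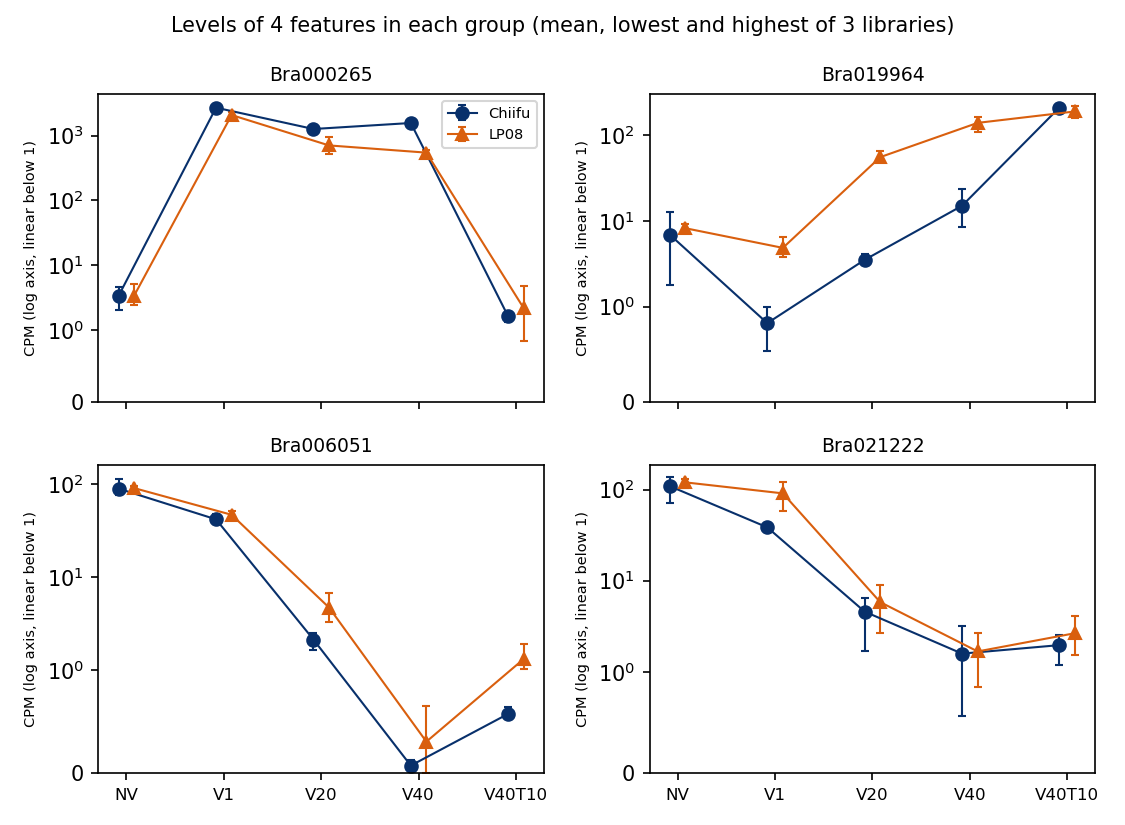
Levels of 4 features in CPM (log axis, linear below 1) in the 5 groups of Chiifu (circles) and LP08 (triangles), as the mean of 3 libraries with bars from the lowest to the highest library. Bra000265 is high only in the cold groups, Bra019964 rises earlier in LP08 than in Chiifu, and Bra006051 and Bra021222 fall through the cold and stay below 3 CPM on average after the warm period.

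The return to warmth was also compared directly with the last time in the cold. In Chiifu 6959 genes were higher and 6444 lower at V40T10 than at V40, and in LP08 7066 and 7205. Both cultivars shared 3189 that rose and 3333 that fell, where independent lists would share 1713 and 1617. Bra000265 fell by 9.92 on the log2 scale in Chiifu (SE 0.51) and fell by 8.04 in LP08 (SE 0.48, with a log2 change of -9.29 without LP08 V40T10 replicate 2), to 1.61 ± 0.236 and 2.15 ± 2.24 CPM. Bra010404 rose from 0.707 ± 0.0703 to 45.4 ± 14.1 CPM in Chiifu and from 3.84 ± 1.5 to 40.6 ± 15.6 CPM in LP08, 63.8-fold and 10.5-fold higher. Among genes that changed by 2-fold or more in Chiifu, 62% were higher, against 51.9% of all called genes, and in LP08 47.9% were higher, against 49.5%. Neither group of this comparison in Chiifu is NV, and 96.5% of the Chiifu calls were kept when the spread came from these groups alone. The Chiifu total of 13403 rose to 17297 in that fit and to 18417 with voom weights per group. The LP08 total of 14271 became 13823 and 15243, so which cultivar had more genes depended on the spread used.

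Whether changes made in the cold lasted was asked by following the genes called at V40. In Chiifu 2433 of the 6106 genes higher at V40 (39.8%) were still higher than NV at V40T10, and 2924 of the 7061 lower genes (41.4%) were still lower. In LP08 these were 1863 of 4985 (37.4%) and 1874 of 5130 (36.5%). Independent lists would share 1207 and 1507 genes in Chiifu and 1013 and 1154 in LP08. Of the genes higher at V40, 3305 in Chiifu (54.1%) and 2866 in LP08 (57.5%) fell between V40 and V40T10, and of those lower at V40, 3853 (54.6%) and 3021 (58.9%) rose. Independent lists would share 1370, 1251, 1711 and 1262, but the V40 libraries that define these genes are also the baseline of the return, which favours a return. In both cultivars at once, 233 genes were higher and 319 lower than NV at all 4 later times, among them Bra006051. A gene that still differed from NV can also be among those that returned in part, as Bra006051 was. From 0.071 CPM at V40 in Chiifu and 0.303 CPM in LP08 it rose 7.63-fold and 4.21-fold (edgeR adjusted p 0.0011 and 0.00126). The Chiifu level lies under the 0.113 to 0.177 CPM that a count of 0 allows, and the lowest LP08 library was at 0. The sizes of these folds are therefore uncertain. With the spread of the compared groups alone, the Chiifu genes still higher or lower were 605 and 814, those that returned were 1789 and 2205, and those at all 4 later times in both cultivars were 80 and 163. In 8 simulated sets with unchanged groups against the same controls no gene was called at V40 or at V40T10, so no overlap could arise there, which leaves open how far shared controls raise the overlap of real changes. Both comparisons share the NV libraries, of which there are too few to give each comparison its own, so part of the excess over independent lists may come from them.

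The last comparisons asked whether the cultivars responded differently. At V1 the response of 2646 genes differed between cultivars (1626 with the higher change in LP08, 1020 with the lower), at V20 that of 2963 (1612 and 1351) and at V40 that of 3522 (1903 and 1619). At V40T10 it was 7819 genes (3843 and 3976), or 27.2% of those tested. Of these, 508 rose in Chiifu and fell in LP08 and 430 did the reverse, while 2136 fell and 1202 rose in LP08 without being called in Chiifu. A further 1641 fell and 857 rose in Chiifu without being called in LP08. Without Chiifu V40T10 replicate 3 the 508 became 309 and the 857 became 568. With the spread of the compared groups alone, the 508 and 430 became 129 and 151, the 2136 became 1364, and the 1641 and 857 became 617 and 271. Bra013714 rose from 59.8 ± 85.1 to 367 ± 115 CPM between NV and V40T10 in Chiifu and fell from 100 ± 67.2 to 1.14 ± 0.721 CPM in LP08 (SD, n = 3 each). The difference of its responses was -9.09 on the log2 scale (SE 1.19, edgeR adjusted p 7.7e-06), and -11.59 without Chiifu NV replicate 2, -8.33 without LP08 NV replicate 2 and -9.69 without LP08 V40T10 replicate 1. Bra030386 moved alike, from 78.4 ± 92.2 to 564 ± 122 CPM in Chiifu and from 131 ± 106 to 2.17 ± 0.448 CPM in LP08, with a difference of -8.75 (SE 1.42), which was -10.38 without Chiifu NV replicate 2 and -7.81 without LP08 NV replicate 2. Bra005229 was at 1.13 ± 0.435 CPM in Chiifu and 36.1 ± 17.1 CPM in LP08 at V40T10, from 3.51 ± 2.21 and 4.48 ± 2.89 CPM at NV. Its difference of 4.63 (SE 0.93, edgeR adjusted p 0.000759) was 5.31 without LP08 NV replicate 1, and was no longer past the threshold with voom weights per group, where the adjusted p was 0.101.

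These 4 counts depended on the spread used. They were 635, 884, 1121 and 4574 with the spread of the compared groups alone, and without Chiifu NV replicate 1 the first 3 became 5170, 5259 and 5899, while the V20 count was 1931 without Chiifu V20 replicate 2. The 1351 genes with the lower change in LP08 at V20 became 873 and 866 without LP08 NV replicates 1 and 2 in turn, and 2073 without Chiifu NV replicate 3. Without Chiifu NV replicates 2 and 3 together, which leaves 1 library with its spread taken from other groups, the 1626 at V1 became 919 and the 1612 at V20 became 1052. The share with the higher change in LP08 then went from 61.5 to 47.9% at V1, from 54.4 to 46.4% at V20 and from 54 to 48.2% at V40. Scaling factors differed at V40T10, with 1.18 to 1.21 in Chiifu and 0.826 to 0.849 in LP08, and with scaling by the library total alone 17.7% of the V40T10 differences were higher in LP08, against 49.1% with the TMM factors, and 74.3% of the V40 differences, against 54%.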

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

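Except for the splits of the libraries behind the interactions, the tests of explanations given here were chosen after the counts were seen.

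Responses to cold differed between the cultivars at all 4 treatments, by an interaction term: 2646 genes at V1, 2963 at V20, 3522 at V40 and 7819 at V40T10. The rise to V40T10 is the first pattern weighed, and spread among the Chiifu NV libraries does not account for it, since with no NV library in the contrast 8733 genes differed in their change from V40 to V40T10, against 1385 from V1 to V20 and 41 from V20 to V40. Nor does unequal depth, with 7575 genes at V40T10 and 3296 at V40 at equal depth, or a wrong scaling factor at V40T10, as log2 shifts of its LP08 libraries from -0.6 to 0.6 left at least 7787 genes, over 1.5 times the V40 counts of 3522 with TMM factors and 3719 with library totals. A wrong factor at V40 is not excluded, as a shift of its LP08 libraries by 0.3 gave 5548 or 6117 genes there, though library totals moved the median of that interaction only from 0.0218 to 0.172. A difference in developmental stage between the early- and the late-flowering cultivar after the warm period may underlie it and stays open, as no label gives the stage of the plants.

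Of 25 splits of the 12 libraries behind each interaction, 24 of them drawn at random, 3 gave as many genes as the real one at V1, 4 at V20, 5 at V40 and 4 at V40T10, the real one included, so these splits do not exclude chance. The highest other splits gave 10051, 9384, 9551 and 14124 genes. Such splits exchange cultivar labels at 1 of the 2 treatments, which turns the constant difference between the cultivars into an interaction. Where that difference cancels, the 10, 10, 4 and 12 splits drawn gave at most 0, 1, 1 and 1 genes, though these splits mix the cultivars within groups, which widens the spread.

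Reads outside the gene counts stood above the NV libraries of their cultivar in all 3 libraries of some groups. Alignments at several places were 5.34 ± 1.69% (SD, n = 3) in LP08 V1, where replicate 2 had 7.29%, and 4.88 ± 0.572% in LP08 V40, against 3.91 ± 0.09% in LP08 NV. Reads on overlapping genes were 0.0441 ± 0.00346% in Chiifu V40T10 against 0.0328 ± 0.00796% in Chiifu NV. In LP08 they were 0.0522 ± 0.00299% at V20, 0.046 ± 0.00317% at V40 and 0.0547 ± 0.00529% at V40T10, against 0.0366 ± 0.00201% at NV. Reads on no gene were 8.63 ± 0.474% in LP08 V40T10 against 7.94 ± 0.168% in LP08 NV.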

How the results depend on the processing

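Counts kept within 1.5 times of their value, in all 15 comparisons, with RLE size factors, no filter on low counts, DESeq2, the replicate block, equal depth and, where it applied, with genes absent from one cultivar removed. RLE kept 95.9 to 99.6% and DESeq2 97.5 to 99.3% of the genes called in each comparison. Replicate numbers did not pair the libraries: 17 of 135 pairs with the same number in different groups had deviations correlated over 0.1, and 9 of 30 libraries were closest to one of their own number. With the number as a block the 15 counts were 12761 for LP08 against Chiifu, 14195, 12442, 12886, 11587 and 13246 for Chiifu at V1, V20, V40, V40T10 and V40T10 against V40, 11875, 11340, 9892, 12082 and 14095 for LP08, and 2446, 2814, 3342 and 7521 for the interactions. No printed feature changed sign, but splits near 50% turned in several comparisons, as in the V40T10 interaction, where 49.1% were higher in LP08, but 53.9% with RLE and 54.2% with DESeq2.

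The spread of the Chiifu NV libraries decided most of what moved. With only the groups compared in the fit, LP08 against Chiifu without cold gave 5121 genes, Chiifu V1, V20, V40 and V40T10 against NV gave 6780, 4996, 5267 and 4312, and the interactions gave 635, 884, 1121 and 4574. LP08 V1, V20, V40 and V40T10 against NV gave 13225, 12890, 10697 and 12737, more than Chiifu each time. V40T10 against V40 gave 17297 in Chiifu and 13823 in LP08. Genes shared by the cultivars' responses, higher and lower, were then 2472 and 2644 at V1, 1600 and 1992 at V20, 1521 and 1854 at V40, and 1148 and 1222 at V40T10. Voom weights per group, chosen after the data were seen, gave 5563 for the cultivars, 7031, 4848, 5348 and 4023 for Chiifu, and 504, 585, 741 and 3735 for the interactions. Shared genes with these weights were 2800 lower at V1, 1666 and 2072 at V20, 1622 and 1953 at V40, and 932 and 1336 at V40T10. Both settings let the wider spread of Chiifu NV count for more than the fit of all groups does. The fit of the compared groups still averages it with the other groups compared, while the voom weights are set by group. Of the genes called in the comparisons with Chiifu NV, 18.1 to 48.2% were kept under the voom weights. In LP08 and in V40T10 against V40, 96.3 to 99.9% were kept.

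A minimum log2 fold change of 1, which keeps fewer genes by its construction, left 7100 for the cultivars, 7956, 6519, 6870, 5548 and 6961 for Chiifu at V1, V20, V40, V40T10 and V40T10 against V40, and 6080, 5916, 5104, 6421 and 7945 for LP08. Shared genes were then 1776 and 2011 at V1, 1304 and 1806 at V20, 1108 and 1643 at V40, and 1130 and 723 at V40T10.

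With 1 library left out, the interaction count ran from 1852 to 5170 at V1, from 1931 to 5259 at V20 and from 2588 to 5899 at V40, each time highest without Chiifu NV replicate 1. The cause of these lows and highs was not tested. Without Chiifu NV replicates 2 and 3 the majority of the V1, V20 and V40 interactions turned to lower in LP08. Scaling by the library total moved the median of all genes in the V40T10 interaction from 0.0046 to -0.428 on the log2 scale. Of the features whose levels are printed, Bra005229 missed the threshold with voom weights. Bra030917, named without its levels, missed it without Chiifu NV replicate 2. Tests of the gene lists and of the copies of FLC, FT, SOC1 and VIN3, with their alternatives, were not run, as the reference names none of them. Equal depth at 16926920 counts left 2489, 2762, 3296 and 7575 interaction genes, greater depth could not be tested, and features under 0.113 to 0.177 CPM per library cannot be told from 0.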

Other observations

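The tests and comparisons in this part were chosen after the data were seen.

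The transcriptome moved little between 20 and 40 days of cold. In Chiifu 75 genes differed between V20 and V40 (45 higher and 30 lower), and in LP08 588 (322 and 266), where 9536 and 9856 genes differed between V1 and V20. The change from V20 to V40 differed between the cultivars for 41 genes, the change from V1 to V20 for 1385. These counts use the spread of all groups, the wider Chiifu NV included. No fit of the compared groups alone was run for them. Of the 2549 genes higher than NV in both cultivars after the warm period, the V20 response was called higher in LP08 than in Chiifu for 261 and lower for 103, with no call at V20 within a cultivar required. These numbers were 194 and 144 for the V1 response, 239 and 168 for V40 and 213 and 97 for V40T10. Of the 2431 genes lower than NV in both, the response was lower in LP08 than in Chiifu for 76 and higher for 155 at V1, and for 192 and 105 at V20, 176 and 146 at V40 and 238 and 218 at V40T10. Over all genes tested, the differences at V20 split into 1612 higher and 1351 lower in LP08.

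LP08 and Chiifu differed at every treatment, in 12380 genes at V1, 12003 at V20, 12139 at V40 and 16840 at V40T10. A difference of 2-fold or more was present at all 5 treatments for 1173 genes higher and 1835 lower in LP08. At V40T10 alone, with no call between the cultivars at any other treatment, 544 genes were higher and 1129 lower by that margin. The numbers at V40T10 rest on the TMM factors, which differed between the cultivars there. No other scaling was run for them, so their split by direction may depend on it.

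The Chiifu NV libraries differed more from each other than the libraries of any other group. Depth does not account for it, as at 16926920 counts each the lowest deviation of a Chiifu NV library was 0.548 on the log2 scale and the highest of any other library 0.377. LP08 RNA in replicates 2 and 3 is also argued against: of 112 genes with at least 5 CPM in LP08 NV and at most 3 counts over the 12 other Chiifu libraries, 28 had any count in replicate 2 and 22 in replicate 3 (5 in replicate 1), with 1445 and 1487 counts in all (6 in replicate 1), although their summed level, 4.38% and 5.24% of that in LP08 NV, would give each gene about 4.76 and 4.9 counts or more. Plants of other genotypes may be among them, since 17 genes in replicate 2 and 19 in replicate 3, with 2 in common, had at most 3 counts while standing at 5 CPM or more in all cold-treated Chiifu libraries and in another NV library, against 0 in replicate 1 and at most 1 in any cold-treated library, when set beside the other cold-treated groups and its own group. Such genes could also be silent for reasons of the plants' state, and no label tells the seed source, so this stays a hypothesis. By deviation from the group mean, replicates 2 and 3 were not set apart from replicate 1. It was 0.588 on the log2 scale in replicate 1, 0.56 in replicate 2 and 0.709 in replicate 3.

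Without cold, 61.6% of the genes that differed by 2-fold or more were lower in LP08. Counts lowered by sequence differences between LP08 and the reference are argued against as the whole cause, since the shares at V1, V20 and V40 were 52.3 to 53.1%. They stay open for part of it, as 61% of the genes with such a difference at all 5 treatments were lower in LP08, which lasting differences in expression would also give. Whether the spread among the Chiifu NV libraries accounts for part of it cannot be told: without replicates 2 and 3 the share was 56.9%, but this leaves 1 Chiifu NV library, with its spread taken from the other groups, and with 1 of the 3 left out it was 59.2 to 60.1%. At V40T10, where no NV library takes part, the share was 59.4% with the TMM factors, the only scaling run for it, so a difference between the cultivars in warmth stays open too.

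For each comparison of 2 groups of 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes as the real one. LP08 against Chiifu without cold gave 12932 genes and 1179 in the highest other split. Chiifu V1, V20, V40 and V40T10 against NV and V40T10 against V40 gave 14401, 12690, 13167, 11802 and 13403, with 1280, 1291, 795, 90 and 0 in the highest other splits. In LP08 these were 12127, 11521, 10115, 12292 and 14271, with 0, 7, 0, 1 and 5. Every other split mixes libraries of both groups, which widens the spread and shrinks the difference. Low counts there would follow from any difference between the groups, whatever its cause, so these gaps decide nothing about it.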
